A study of Mus musculus with 9 samples.

How the data were processed

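The study measured gene expression by RNA sequencing in Osx1-Cre cells of newborn mouse calvaria, the flat bones of the skull roof. Osx1-Cre is a transgene that expresses Cre recombinase under the promoter of osterix (Sp7), a transcription factor of the osteoblast lineage, so that the sort is meant to select bone-forming cells and their precursors. Per the labels, the cells were sorted by flow cytometry, cultured in medium with 10% serum, and harvested at 90% confluence, and each library came from the cells of 3 to 5 pups aged 2 to 4 days. There were 5 libraries labelled IRE1KO and 4 labelled WT. IRE1, encoded by Ern1, is a kinase and endoribonuclease of the endoplasmic reticulum membrane that splices Xbp1 mRNA during the unfolded protein response. Per the labels' protocols, polyadenylated RNA was made into strand-marked libraries, and all libraries were prepared and sequenced on a NextSeq instrument in 1 batch, so no library or sequencing batch could be set against the genotype; litter, sort and culture day are not in the labels and could align with it. Since the labels call each such pool 1 biological replicate, the spread between libraries includes biological variation.

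The authors deposited a table of raw counts, whole numbers of reads per gene and library, with no normalization. STAR, limma and the mm10 genome build are named per the submitters' processing notes, without versions or roles. The counting program, the annotation release and the strand setting are not given in the sources used here, so that counts of overlapping or antisense genes, and of close relatives within gene families, could be shared. The table held 25860 genes and 13 mitochondrially encoded genes among them had 0 counts in every library. Gene positions were taken by Ensembl identifier from GENCODE M21 on GRCm38, the assembly that mm10 also names, and 24957 genes had one. The release need not be the one the authors counted with.

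Total counts ranged from 18784636 to 22028075 per library, and the 20 most abundant genes took 9.9% to 12.8% of them. A count of 3, taken as the floor, corresponded to 0.136 to 0.16 CPM, the count scaled to library size. Intervals on counts cover counting error only.

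Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Files were prepared in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Genes were kept with edgeR's filterByExpr, which left 13712 for testing, and libraries were scaled by TMM. Expression was compared with edgeR's quasi-likelihood test with robust dispersion, genotype being the sole term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are IRE1KO over WT, and CPM values are given as mean ± SD over the libraries of a group.

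The design, the gene lists, the naming rule and the alternatives below were fixed before the data were examined. Named genes were Ern1, Ern2, Xbp1, Dnajb9, Hspa5, Ddit3, Bloc1s1, Runx2, Sp7, Alpl, Bglap, Tnfsf11, Tnfrsf11b, Cdkn1a and Cdkn2a. To these were added, per direction, the 10 passing genes with the largest fold change among those with a mean of at least 5 CPM and no predicted-gene symbol. For each list the 4 members with the smallest p were named if any member passed, and otherwise the 2 with the smallest p. Genes named outside this rule were chosen after their values were seen. Some genes that the rule takes are not reported here, and they were taken out of the refits of named genes and the search for outlying libraries after the results were seen.

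The 24 gene lists covered the unfolded protein response (XBP1s targets, ATF6-type chaperones, PERK-ATF4-CHOP targets, reported substrates of regulated IRE1-dependent decay), bone (osteoblast differentiation, osteoclast-supporting signals, collagens and collagen processing, suture and periosteal progenitors), senescence, cell cycle, beta-catenin targets, NF-kB targets, interferon-stimulated genes, cholesterol synthesis, glycolysis and hypoxia, and markers of cells that the culture could also hold (chondrocytes, adipocytes, macrophages and osteoclasts, endothelium, skeletal muscle, glia and pigment cells, erythroid cells), with mitochondrially encoded and Y-linked genes. Members absent under their current symbol were matched by identifier or older symbol. Lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Called genes within 10 Mb of Ern1 were compared with all other tested genes by Fisher's exact test, two-sided.

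The steps were tested on simulated counts with 5 and 4 libraries and 200 changed genes among 13712. Of the changed genes, 63% were recovered at 1.5-fold, 82% at 2-fold and 96% at 4-fold, and 5.59% of the 161 calls were false. Random lists without change passed at an unadjusted p of 0.05 in 6 of 100 cases, and 10 of 10 shifted lists were called. The simulated genes were drawn independently of one another and with the same dispersion in both genotypes. These rates therefore need not hold for lists of co-expressed genes, or where WT libraries vary more than IRE1KO libraries.

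Alternatives were other scalings (DESeq2's size factors, upper quartile, library totals), other filters, DESeq2, limma voom with and without sample weights, a non-robust fit, the replicate number as a block, Y-linked expression as a covariate, the omission of each library, other list tests and other windows. After the data were seen, 4 more were added: omission of WT libraries 1 and 4 together, summing of IRE1KO libraries 3 and 5, and covariates for glial and interferon-stimulated genes. No library was left out of the main comparison. Each library was counted separately, as the labels call it a biological replicate. The closest pair, IRE1KO libraries 3 and 5, differed by 1.92 times the sampling variance of their counts, the next pair by 4.03 times. This is more than counting noise, so they are not taken as 1 library deposited again, but it does not show that they came from different pools.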

Results

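Gene expression was profiled in cultured Osx1-Cre calvarial cells from newborn mice, with 5 IRE1KO and 4 WT libraries of 18784636 to 22028075 counts each. The comparison asks what loss of IRE1, the stress sensor of the endoplasmic reticulum, changes in cells of the osteoblast lineage. The cultures had a mesenchymal, matrix-producing profile: Col1a1, a chain of type I collagen, reached 23304 ± 1126 CPM (SD, n = 5) in IRE1KO and 20395 ± 7219 CPM (SD, n = 4) in WT. Transcripts of mature osteoblasts and osteocytes were scarce. Bglap (osteocalcin) was near the detection limit at 0.10 ± 0.078 CPM (SD, n = 5) in IRE1KO and 0.039 ± 0.049 CPM (SD, n = 4) in WT, while Ibsp, bone sialoprotein, was at 0.546 ± 0.390 and 2.29 ± 1.29 CPM (adjusted p = 0.152 over all genes, edgeR) and the osteocyte gene Dmp1, which was too low to test, at 0.281 ± 0.177 and 1.26 ± 0.690 CPM. WT libraries differed from one another more than IRE1KO libraries did: the variance between 2 libraries was 15.4 to 112.3 times sampling noise within WT and 1.92 to 10.0 times within IRE1KO. The first principal component held 45.9% of the variance and placed WT library 4 at 56.7, against -23.4 to 15.1 for the other libraries.

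Ern1 itself, on chromosome 11 from 106394650 to 106487852 (GRCm38, ENSMUSG00000020715), was not lower in the IRE1KO libraries. Its level was 49.8 to 55.8 CPM in the 5 IRE1KO libraries and 41.5 to 54.2 CPM in the 4 WT libraries (log2 fold change 0.17 ± 0.076 SE, adjusted p = 0.306, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The deposited count is a total per gene, so it does not show whether some exons are missing, and it neither checks nor contradicts the genotype labels. Without WT library 1 the log2 fold change was 0.24, with an adjusted p of 0.0467 in the same edgeR test. Ern2, the gut paralog of Ern1, had 0 counts in every library.

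At an adjusted p under 0.05, IRE1KO cells differed from WT in 87 of 13712 tested genes. An unadjusted p under 0.05 was reached by 2263 genes in the same edgeR test, so the 87 need not be all that differ. Il1rl1 (the interleukin-33 receptor), Fgf9 and Gdf6 (growth factors) and the chemokines Cxcl5 and Cxcl14 were among the genes that rose. Lpl and Plin4, which act in lipid handling, Ngfr, a neurotrophin receptor, and Id1, a transcriptional target of BMP signalling, were among those that fell. In all, 35 genes rose and 52 fell out of 13712 tested at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 16 and 39 of them changed at least 1.5-fold. The groups did not overlap for any of these 87 genes, nor for 950 (6.93%) of the tested genes, against 1.59% by chance. The count depended on which libraries were included. It was 6, 2, 8, 8 and 3 without IRE1KO libraries 1 to 5 in turn, and 1192, 7, 3 and 399 without WT libraries 1 to 4. With IRE1KO libraries 3 and 5, the closest pair, summed and counted as 1 library, it was 10. Genes at an unadjusted p under 0.05 in edgeR varied less, from 1607 without WT library 3 to 3916 without WT library 1. Of the 87 genes, 76 passed in at most 2 of the 9 fits that left out 1 library. Il1rl1, Fgf9, Gdf6, Cxcl5, Lpl, Plin4 and Ngfr were among these, while Cxcl14 passed in 4 of the fits and Id1 in all 9. DESeq2 called 583 genes and limma voom 16, the 87 being among the 583 and all 16 among the 87.

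**Figure D1:**
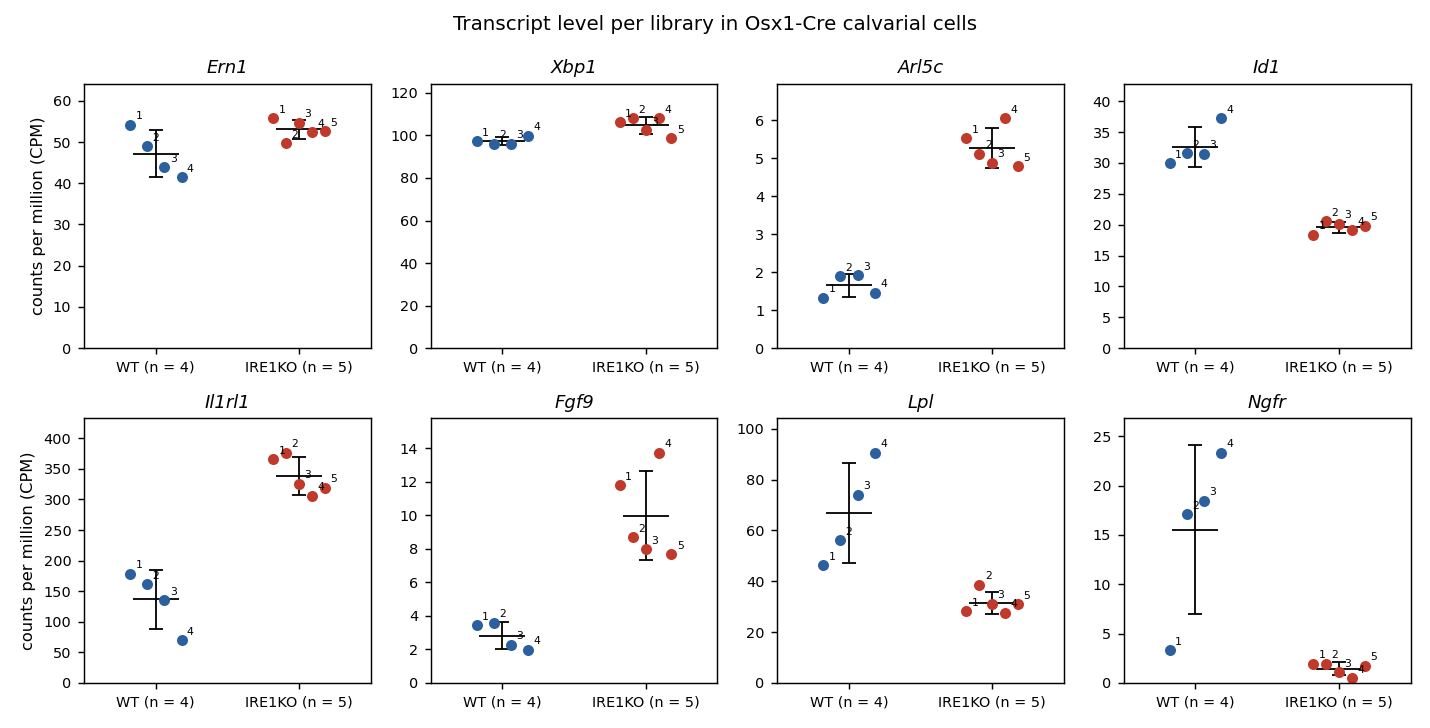
Level of 8 genes in CPM (vertical axes, each from 0) in the 4 WT and 5 IRE1KO libraries. Points are libraries with their replicate numbers, and bars are the mean ± SD; Ern1 overlaps between groups (41.5 to 54.2 CPM in WT, 49.8 to 55.8 CPM in IRE1KO), while Arl5c, Id1, Il1rl1, Fgf9, Lpl and Ngfr do not.

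Among the genes that rose, with a mean of at least 5 CPM, Fgf9 went from 2.82 ± 0.807 CPM in WT (SD, n = 4) to 9.97 ± 2.66 CPM in IRE1KO (SD, n = 5), a 3.53-fold difference (log2 fold change 1.82 ± 0.25 SE). Il1rl1 rose from 136.4 ± 47.9 to 338.7 ± 30.8 CPM, or 2.48-fold, and Gdf6, which encodes a BMP-family growth factor, from 7.50 ± 2.08 to 16.8 ± 1.46 CPM, or 2.24-fold. Cxcl14 and Cxcl5 rose 1.94-fold and 1.89-fold, to 86.7 ± 16.9 and 175.0 ± 33.3 CPM. The other leading genes were Tmem90b (1.93-fold), Wdfy1 (1.85-fold), Abca5 (1.79-fold), Nfatc2 (1.68-fold), a transcription factor activated by calcineurin, and Runx3 (1.58-fold), a relative of Runx2. Vdr, the vitamin D receptor, also rose, from 72.9 ± 3.71 to 100.2 ± 9.34 CPM. It was chosen after its value was seen.

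Among the genes that fell, Ngfr, the p75 neurotrophin receptor, went from 15.5 ± 8.57 CPM in WT to 1.43 ± 0.652 CPM in IRE1KO (log2 fold change -3.44 ± 0.56 SE). Olfml2a (-2.61), Cadm4 (-2.25) and Col15a1 (-2.11), a basement membrane collagen, followed on the log2 scale. Wnk4, which encodes a kinase that regulates ion transport and lies 5.12 Mb from Ern1, fell by 2.03. Aldh1a7 (-1.56), Plin4 (-1.49), Atp10d (-1.32), Itih2 (-1.25) and Lpl (-1.09) completed the 10 largest decreases among genes with a mean of at least 5 CPM. In WT library 1, Ngfr, Olfml2a, Cadm4 and Col15a1 were at 3.32, 4.44, 4.44 and 11.6 CPM, closer to IRE1KO than in the other WT libraries. The other WT libraries had at least 17.1, 12.9, 16.2 and 35.3 CPM, and the IRE1KO libraries at most 1.95, 3.53, 3.49 and 8.82 CPM. Aldh1a7 has close relatives with which reads could be shared, and Atp10d is annotated as a polymorphic pseudogene. Id1 fell by 0.73 ± 0.068 SE, from 32.6 ± 3.22 to 19.6 ± 0.869 CPM, with an adjusted p of 0.00928 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Id1 and Arl5c were the genes that passed after the omission of any 1 of the 9 libraries, and both were chosen after their values were seen.

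Genes close to Ern1 were over-represented among those that changed. Of 275 tested genes within 10 Mb of Ern1, 15 changed (5.45%), against 72 of 13315 elsewhere (0.541%), an odds ratio of 10.6 with a 95% interval of 5.57 to 18.98 (Fisher's exact test, two-sided, p = 1.91e-10). The odds ratio was 2.03 without WT library 1 (44 of 278 genes, or 15.8%, against 8.47% elsewhere), 2.98 without WT library 4 (22 of 279) and 48.5 to 97.5 without any 1 of the other libraries, where 1 to 4 genes near Ern1 were called. Of the 15, 7 were higher and 8 lower in IRE1KO. Arl5c, which encodes a small GTPase of the Arf family and lies 8.4 Mb away, rose from 1.65 ± 0.302 to 5.28 ± 0.522 CPM. Abca6 and Abca5, neighbouring transporter genes, went in opposite directions, by -3.28 and 0.84 on the log2 scale, while Igfbp4, an insulin-like growth factor binding protein, fell by 0.62. By distance, 1 of 40 tested genes changed within 2 Mb, 9 of 70 between 2 and 5 Mb and 5 of 165 between 5 and 10 Mb. In the 2 Mb window the odds ratio was 4.01 and did not pass (Fisher's exact p = 0.227). With 1 call among 40 genes, that window cannot show whether the enrichment holds so close to Ern1. Neighbouring genes are not independent, so that the p-values of Fisher's test are too small.

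**Figure D2:**
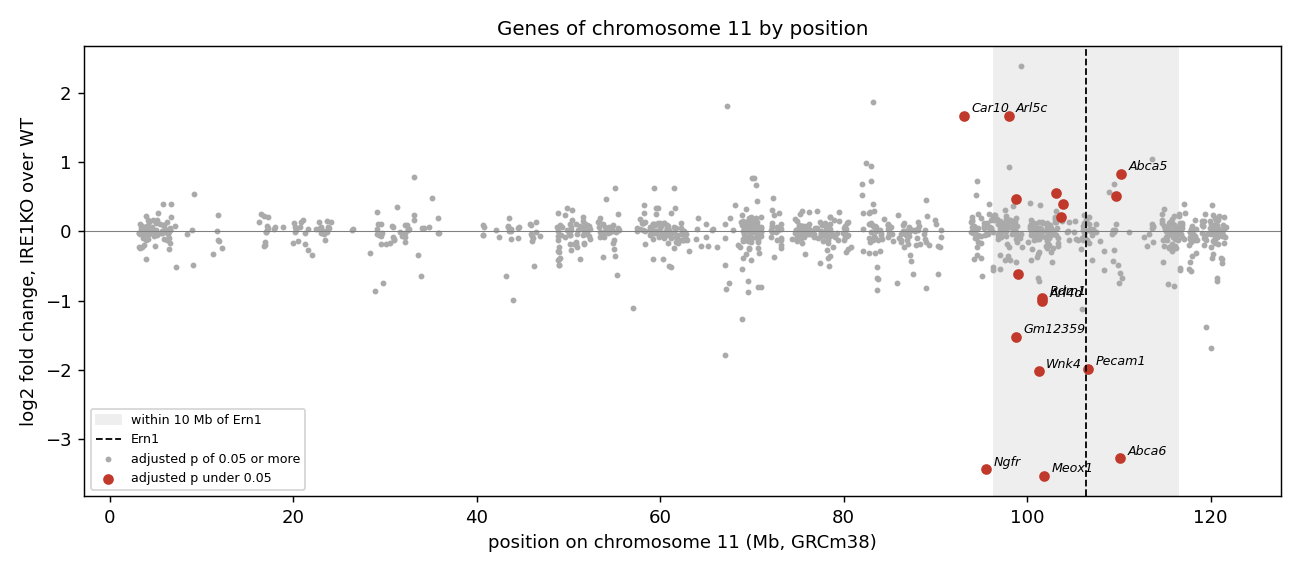
Log2 fold change of IRE1KO over WT (vertical axis) for the tested genes of chromosome 11 by start position in Mb on GRCm38 (horizontal axis), with the 10 Mb on each side of Ern1 shaded. Red points passed the threshold and lie mostly in the shaded region, where 15 of 275 tested genes did so, in both directions.

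Among markers of other cell types, the adipocyte, glial and chondrocyte lists were lower in IRE1KO at the preset correlation, and the chondrocyte list is described further below. Of the adipocyte markers with 6 tested members, 3 fell and 3 did not pass over all genes, and 4 fell when adjusted over the list alone. Plin4, a lipid droplet protein, fell by 1.49, Lpl, the lipoprotein lipase, by 1.09 and Fabp4, a fatty acid binding protein, by 1.44 on the log2 scale, while Pparg, the master regulator of adipocyte differentiation, had a log2 fold change of -0.47 ± 0.13 SE. The list was lower with a camera adjusted p of 1.79e-07, which was lost at adjusted p = 0.104 with an estimated correlation. Adipoq, a product of mature adipocytes that was too low to test, was at 0.229 ± 0.204 CPM (SD, n = 4) in WT. Of 9 tested glial and pigment cell markers, none passed over all genes and 6 fell when adjusted over the list alone. S100b had a log2 fold change of -0.93 ± 0.18 SE and Cdh19, an adhesion protein of Schwann cell precursors, -3.34 ± 0.65 SE. The list was lower with a camera adjusted p of 2.64e-06, lost at adjusted p = 0.148 with an estimated correlation. WT library 1 had a glial score of -0.66 relative to the WT mean, closer than any other WT library to the IRE1KO libraries at -1.54 to -0.85.

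**Figure D3:**
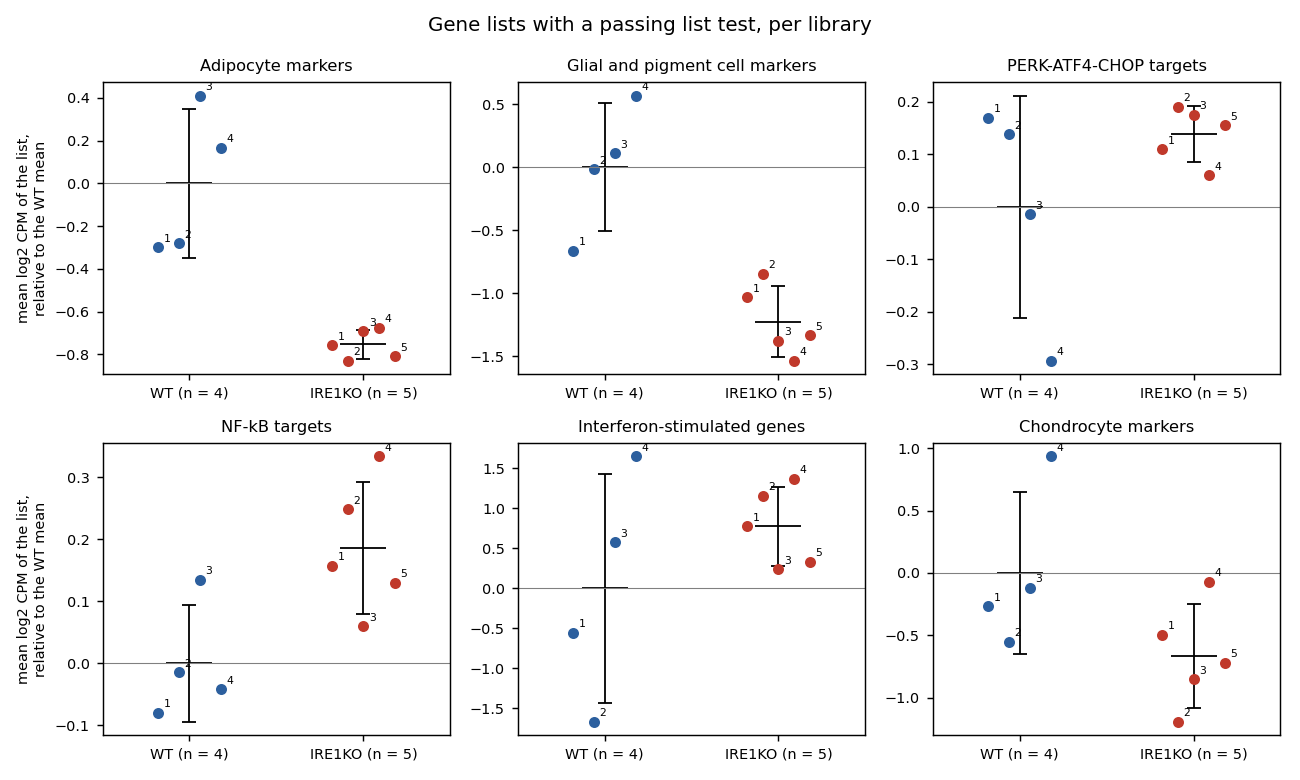
Mean log2 CPM of the tested members of 6 lists relative to the WT mean (vertical axes) in the 4 WT and 5 IRE1KO libraries. Points are libraries with their replicate numbers and bars the mean ± SD; adipocyte and glial scores do not overlap between the groups, while the WT scores of the interferon-stimulated genes run from -1.67 to 1.65 around all IRE1KO libraries.

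Genes of the unfolded protein response differed little. None of 40 tested XBP1s targets passed over all genes or when adjusted over the list alone, and the list had a median log2 fold change of 0.047 and a camera adjusted p of 0.104. Xbp1 was at 104.7 ± 4.04 CPM in IRE1KO and 97.4 ± 1.76 CPM in WT (adjusted p = 0.218, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a total that does not separate spliced from unspliced mRNA. Dnajb9, a co-chaperone and classical XBP1s target, had a log2 fold change of -0.080 ± 0.050 SE, Pdia6 of -0.22 ± 0.062 SE and Serp1 of 0.10 ± 0.031 SE. The XBP1s list passed without IRE1KO library 3 (camera adjusted p = 0.0282) and without WT library 4 (camera adjusted p = 0.00592), in the upward direction. None of 16 tested ATF6-type chaperones passed by either adjustment. Hspa5 (BiP) was at 859.9 ± 26.4 CPM in IRE1KO and 825.8 ± 34.7 CPM in WT, and Manf at 143.1 ± 4.36 and 131.1 ± 8.94 CPM. The list's median was 0.0064, its mean -0.0060 and its test upward (camera adjusted p = 0.884).

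Of 32 tested PERK-ATF4-CHOP targets, 1 rose over all genes and when adjusted over the list alone: Ddit4, an inhibitor of mTORC1, by 1.19-fold. Slc7a5 (log2 fold change 0.34 ± 0.098 SE), Cebpb (0.23 ± 0.068 SE), Shmt2 (0.21 ± 0.061 SE) and Ddit3, which encodes CHOP (0.081 ± 0.11 SE), did not pass. The list was higher with a camera adjusted p of 0.000227, lost at adjusted p = 0.632 with an estimated correlation, and lost without WT library 4 (camera adjusted p = 0.143). Other splits of the libraries gave as small a camera p in 28 of 100 draws with the real split included. None of 11 tested reported substrates of regulated IRE1-dependent decay passed by either adjustment. Bloc1s1, the most widely used of them, had a log2 fold change of -0.063 ± 0.059 SE, Sparc of 0.25 ± 0.079 SE and Pmp22 of -0.29 ± 0.11 SE. The median of the list was 0.015 and its mean -0.025, with an upward test (camera adjusted p = 0.769).

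Osteoblast genes did not pass over all genes in any of 23 tested cases, while 3 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.49986). Runx2 (log2 fold change 0.021 ± 0.062 SE) and Sp7 (-0.024 ± 0.17 SE), the lineage's transcription factors, and Alpl (-0.23 ± 0.14 SE), the alkaline phosphatase, did not pass by either adjustment, while Cadm1 (-1.84 ± 0.39 SE) and Wif1 (-0.81 ± 0.18 SE) were among those that fell over the list alone. Of 15 tested osteoclast-supporting signals, none passed over all genes and 1 rose when adjusted over the list alone (camera adjusted p = 0.303). That was Tnfsf11 (RANKL), at 14.3 ± 0.663 CPM in IRE1KO and 10.3 ± 2.08 CPM in WT, with an adjusted p of 0.110 over all genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its decoy receptor Tnfrsf11b had a log2 fold change of -0.12 ± 0.052 SE and Efnb2 of 0.18 ± 0.059 SE.

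Of 34 tested collagen and collagen-processing genes, Col15a1 fell over all genes, and 2 rose and 1 fell when adjusted over the list alone. Lox, which cross-links collagen, was at 2676 ± 82.9 CPM in IRE1KO and 1835 ± 368.7 CPM in WT, Col5a1 had a log2 fold change of 0.32 ± 0.079 SE and Serpinh1, a collagen chaperone, of 0.20 ± 0.064 SE. The list's median was 0.047, its mean -0.041 and its test upward (camera adjusted p = 0.0655). It passed without IRE1KO library 1 (camera adjusted p = 0.0498), without IRE1KO library 3 (camera adjusted p = 0.0282) and without WT library 4 (camera adjusted p = 2.89e-06). Of 17 tested progenitor genes none passed over all genes, and 1 rose and 2 fell when adjusted over the list alone (median 0.067, mean -0.025, upward test, camera adjusted p = 0.400). Axin2, also a beta-catenin target, had a log2 fold change of 0.57 ± 0.11 SE and Mcam of -1.05 ± 0.25 SE. Axin2 lies 2.43 Mb from Ern1, within the window where changed genes were over-represented. Of 11 tested beta-catenin targets none passed over all genes and 1 rose when adjusted over the list alone (median 0.072, mean -0.10, upward test, camera adjusted p = 0.364), and Apcdd1 had a log2 fold change of 0.33 ± 0.14 SE.

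Of 27 tested senescence genes, Cxcl5 rose and Igfbp4 fell over all genes, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.140). Cdkn1a (p21), at 423.7 ± 20.8 CPM in IRE1KO and 349.7 ± 92.3 CPM in WT, and Cdkn2a (log2 fold change -0.29 ± 0.19 SE) did not pass by either adjustment, nor did Timp1 (0.49 ± 0.16 SE), while Cxcl1 (0.61 ± 0.14 SE) rose over the list alone. The list passed without IRE1KO library 3 (camera adjusted p = 0.0371) and without WT library 3 (camera adjusted p = 0.0343). Of 20 tested NF-kB targets, Cxcl5 rose over all genes and 2 rose when adjusted over the list alone, while Nfkb2 (0.19 ± 0.059 SE) and Cxcl2 (0.92 ± 0.32 SE) did not pass over all genes. The list was higher with a camera adjusted p of 0.00829, lost at adjusted p = 0.632 with an estimated correlation, lost without WT library 1 (camera adjusted p = 0.265), and matched in 19 of 100 splits with the real one included.

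None of 26 interferon-stimulated genes passed over all genes or when adjusted over the list alone. Mx2 was at 15.5 ± 8.82 CPM in IRE1KO and 8.38 ± 8.73 CPM in WT, and Ifi27l1 had a log2 fold change of 0.18 ± 0.093 SE. The list was higher with a camera adjusted p of 0.00103, lost at adjusted p = 0.641 with an estimated correlation, lost without WT library 1 (camera adjusted p = 0.208) or WT library 2 (camera adjusted p = 0.290), and matched in 56 of 100 splits. None of 15 tested chondrocyte markers passed by either adjustment, although 14 had negative fold changes. Lect1 was at 0.301 ± 0.376 CPM in IRE1KO and 3.36 ± 4.399 CPM in WT, and Comp, a cartilage matrix protein, at 23.6 ± 10.8 and 62.8 ± 39.4 CPM. Col2a1, the cartilage collagen, was abundant in both, at 1089 ± 268 CPM in IRE1KO and 1235 ± 92.3 CPM in WT (adjusted p = 0.662, edgeR). The list was lower with a camera adjusted p of 0.00132, lost at adjusted p = 0.632 with an estimated correlation, lost without WT library 4 (camera adjusted p = 0.143), and matched in 38 of 100 splits.

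Among the remaining lists no call was made. Of 9 tested endothelial markers, Pecam1, which lies 0.17 Mb from Ern1, fell from 0.719 ± 0.167 to 0.174 ± 0.0902 CPM over all genes and when adjusted over the list alone, while Flt1 had a log2 fold change of 0.87 ± 0.29 SE, Erg of -1.05 ± 0.49 SE and Cdh5 of -0.35 ± 0.24 SE (camera adjusted p = 0.184). No gene passed over all genes among 31 cell cycle genes (camera adjusted p = 0.615; Cenpf at 78.7 ± 5.15 CPM in IRE1KO and 90.6 ± 10.0 CPM in WT, Mcm7 at 67.7 ± 4.30 and 62.8 ± 4.20 CPM), 21 cholesterol synthesis genes (camera adjusted p = 0.49986) or 16 macrophage and osteoclast markers (camera adjusted p = 0.349; Cd52 0.60 ± 0.44 SE and Mrc1 -0.26 ± 0.39 SE on the log2 scale), nor when adjusted over the list alone. Of 19 glycolysis and hypoxia genes, none passed over all genes and 1 fell when adjusted over the list alone, with Bnip3 at -0.24 ± 0.055 SE and Car9 at -0.73 ± 0.32 SE (median 0.054, mean -0.056, upward test, camera adjusted p = 0.725). Neither adjustment gave a call among 9 skeletal muscle markers (camera adjusted p = 0.131; Actc1 -1.77 ± 0.60 SE, Mylpf -0.76 ± 0.36 SE) or 4 Y-linked genes (median -0.022, mean -0.039, upward test, camera adjusted p = 0.725; Kdm5d -0.19 ± 0.47 SE, Ddx3y 0.076 ± 0.40 SE). Erythroid and mitochondrially encoded genes had 0 tested members. The pools differed in sex, since Xist ranged from 26.8 CPM in WT library 4 to 496.5 CPM in WT library 1, and with Y-linked expression as a covariate edgeR called 952 genes.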

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

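The search for libraries far from the rest of their group followed a rule fixed beforehand, while the set of genes it covered was reduced after the result was seen. Of 204 groups of values examined (total counts, the named genes, Xist and the list scores, each in IRE1KO and WT), 8 held a library whose gap to its nearest neighbour took more of the group's range than Dixon's 95% critical value allows, where chance gives 10.2. The number is therefore what chance gives, and none of the 8 is weighed further.

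In IRE1KO library 2, Runx2 was at 63.65 CPM against 68.7 to 69.4 in the other IRE1KO libraries. In IRE1KO library 3, Manf was at 135.3 CPM against 144.3 to 145.7 and Fabp4 at 1.647 CPM against 0.871 to 1.00. Lect1 stood at 0.9572 CPM in IRE1KO library 4, where the others had 0 to 0.213, and Serp1 at 135.7 CPM in IRE1KO library 5, where the others had 138.0 to 138.7. WT library 4 had Tnfrsf11b at 56.7 CPM, below the 64.7 to 65.3 of the other WT libraries, and Erg at 8.728 CPM, above their 1.59 to 2.68. Actc1 was at 3.644 CPM in WT library 2 and 0.808 to 1.18 in the other WT libraries.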

How the results depend on the processing

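The alternatives added after the data were seen were the omission of WT libraries 1 and 4 together, the summing of IRE1KO libraries 3 and 5, and the glial and interferon covariates; the others were planned. The number of called genes depended on nearly every choice that changes the spread between libraries, and apart from the part of WT library 1 its cause was not tested. For the named genes other than Ern1, 1445 values under the alternatives stayed on their side of the threshold, 285 lost the call, 110 gained one and 0 reversed. The 1445 include values called in neither fit. Since the groups did not overlap for any called gene, leaving out 1 library could hardly reverse one, so the 0 says little about stability. Over the lists 495 stayed, 25 lost the call, 27 gained one and 3 reversed. Values called in neither fit changed sign 62 times, genes and lists together. Depth was similar in all libraries, so it limits genes near 0.136 to 0.16 CPM rather than the comparison.

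DESeq2's size factors left 87 calls. Calls fell to 46 with upper quartile scaling (18 higher, 28 lower), 46 with library totals (16 and 30), 45 without a filter (18 and 27), 16 with limma voom (6 and 10) and 55 with at least 1.5-fold change (16 higher). They rose to 583 with DESeq2 (230 and 353), 730 with limma voom and sample weights (285 and 445) and 952 with the Y-linked covariate (389 and 563). Leaving out 1 library at a time gave 2 to 1192 calls, 1 to 466 higher and 1 to 726 lower, 1192 without WT library 1 and 399 without WT library 4, and both of these held all 87 genes. Without WT libraries 1 and 4 together there were 1481 (591 and 890), with IRE1KO libraries 3 and 5 summed 10 (4 and 6), and with the interferon covariate 1781 (798 and 983). With the glial covariate, which largely follows the genotype, edgeR called 0 genes (0 higher, 0 lower), with 1984 at an unadjusted p under 0.05.

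The replicate block over numbers 1 to 4 gave 0 calls in edgeR (0 higher, 0 lower), with 1594 genes at an unadjusted p under 0.05, and leaves out IRE1KO library 5. Without the block and also without IRE1KO library 5, edgeR called 3 genes. Over all libraries and without the block, DESeq2 called 583 and limma voom 16. Same-numbered libraries had correlations of 0.15, -0.20, -0.19 and 0.47 in their deviations from the group means. WT libraries 1 and 4 correlated best with their own number, and WT libraries 2 and 3 did not. The numbers were therefore not taken to pair the samples. With so few libraries the check cannot exclude that same-numbered libraries shared a litter, sort or culture day.

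The enrichment near Ern1 had a Fisher's exact p of 0.227 in the 2 Mb window, 5.40e-09 in the 20 Mb window and 0.0401 at most when 1 library was left out. Its odds ratio of 10.6 was 2.03 without WT library 1, 2.98 without WT library 4, 1.67 without both, 2.89 with DESeq2, 2.58 with limma voom and sample weights, 2.27 with the Y-linked covariate and 1.77 with the interferon covariate, the settings with the most calls. It could not be computed for the replicate block and the glial covariate, where no gene was called. For Ern1 the log2 fold change lay between 0.11 and 0.24 without 1 library, reaching 0.24 with an adjusted p of 0.0467 (edgeR, Benjamini-Hochberg) without WT library 1, and it was 0.24 (adjusted p = 0.0352) with the interferon covariate and -0.13 (adjusted p = 0.559) with the glial covariate.

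With an estimated correlation the camera adjusted p was 0.632 for PERK-ATF4-CHOP, NF-kB and chondrocyte lists, 0.641 for interferon-stimulated genes, 0.104 for adipocyte and 0.148 for glial markers. The adjusted p of fry, a different list test, was 0.401 for PERK-ATF4-CHOP targets and chondrocyte markers, 0.179 for NF-kB targets and 0.538 for interferon-stimulated genes. By fry the adipocyte and glial lists passed (0.0224 and 0.0276). The remaining values are camera adjusted p. Collagens passed with library totals (0.04999), no filter (0.0314), limma voom (0.0401), sample weights (0.00539), both WT libraries out (0.00175), IRE1KO libraries summed (0.0410) and the glial covariate (5.62e-06). XBP1s targets passed with sample weights (0.0234), both WT libraries out (0.0419), IRE1KO libraries summed (0.0395) and the glial covariate (0.00181), under which reported IRE1-dependent decay substrates passed too (0.00127). NF-kB targets were lost with sample weights (0.304), the Y-linked covariate (0.0864), both WT libraries out (0.491) and the interferon covariate (0.247), and chondrocyte markers with sample weights (0.104), both WT libraries out (0.491) and the glial covariate (0.628). The glial covariate also ended the adipocyte (0.0938) and glial (0.805) calls and reversed PERK-ATF4-CHOP targets (0.170), cell cycle (9.96e-05) and glycolysis and hypoxia (0.0104), and the interferon covariate ended the interferon call (0.790). Leaving out 1 library gave ranges of 2.89e-06 to 0.328 for collagens, 0.00592 to 0.305 for XBP1s targets, 0.0343 to 0.451 for senescence genes, 4.98e-06 to 0.143 for PERK-ATF4-CHOP targets, 0.000327 to 0.265 for NF-kB targets, 8.40e-11 to 0.290 for interferon-stimulated genes, 0.000100 to 0.143 for chondrocyte markers, 2.93e-08 to 4.05e-06 for adipocyte markers and 2.93e-08 to 0.000200 for glial markers.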

Other observations

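The tests chosen only after the result was seen were those of the genes near Ern1 by splits and by windows, of WT library 1 as a mislabelled library or one with fewer glial cells, of a larger share of the main cell type, of the PERK-ATF4-CHOP, NF-kB, interferon and chondrocyte lists singly by splits, and of the interferon and macrophage scores. The lists of BMP-SMAD, PPAR and Schwann cell genes were added after the data were seen.

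Of 16 BMP-SMAD target genes, 2 fell: Id1 and Dlx2, the latter from 13.3 ± 1.67 to 7.78 ± 1.09 CPM. The feedback inhibitors Smad6 (-0.23 ± 0.086 SE on the log2 scale), Smad7 (-0.36 ± 0.18 SE), Bambi (-0.37 ± 0.086 SE) and Nog (-0.20 ± 0.22 SE) did not pass, and Id3 (-0.47 ± 0.097 SE), Id2 (-0.62 ± 0.15 SE) and Smad9 (-0.30 ± 0.096 SE) did not either. Gdf6, a ligand, and Bmper, which modulates BMP ligands, rose, the latter from 82.0 ± 5.71 to 116.7 ± 12.3 CPM. Reduced BMP-SMAD signalling may underlie this, and 12 of the 16 had negative fold changes (limma's camera, adjusted p = 1.61e-06 over the 4 added lists), but that list held genes already seen to be lower. The 9 targets whose values had not been looked at had a median log2 fold change of -0.20 (limma's camera, adjusted p = 0.0908), so that the test left the question open.

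Lower adipocyte markers may reflect lower activity of PPAR transcription factors, as Pdk4, one of their targets, also fell, from 79.3 ± 9.59 to 46.8 ± 5.92 CPM. Yet 18 PPAR target genes of fatty acid use had a median log2 fold change of -0.014, with 11 negative and none called (limma's camera, adjusted p = 0.265), which left this open with no sign of a broad decrease. The called count and the adipocyte list exceeded what other groupings gave: of 100 splits of the 9 libraries into 5 and 4, the real one included, 1 gave as many as 87 calls, with at most 1 call in any other split, and 1 gave a camera p as small for adipocyte markers, where the real p was 8.15e-09 and the smallest other 6.72e-07. Chance is thus excluded for the called count at this number of draws, where 1 is the lowest count the draws allow. For the adipocyte list it is not excluded. That list was singled out as the smallest p of those tested, which the count of splits does not allow for. Its call is also lost with an estimated correlation (camera adjusted p = 0.104).

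For 4 other called lists chance is not excluded either. Over the 4, a smallest camera p as small as the real 3.09e-05 came up in 75 of 100 splits, and the smallest other was 7.44e-31. Singly this held in 28 splits for PERK-ATF4-CHOP targets (smallest other p 5.80e-11), 19 for NF-kB targets (3.68e-09), 56 for interferon-stimulated genes (7.44e-31) and 38 for chondrocyte markers (6.74e-15). Splits that gave far smaller values than the genotype point to a structure of the libraries that does not follow it.

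Genes near Ern1 changed more often than elsewhere, in both directions. Other splits called at most 1 gene, so the 87 genes of smallest p were counted instead: 15 lay near Ern1 in the real split and at most 9 in any other, 1 of 100 splits reaching 15 with the real one included, which excludes chance. Expression level is argued against, since 0 of 10000 draws of genes matched on mean expression held 15 called genes, the highest holding 8. Alleles linked to the targeted locus, from a strain other than that of the WT mice, may account for the pattern, as may an effect of Ern1 loss on its neighbours: of 113 other windows of 20 Mb, 0 held as high a called share, the highest being 3.33%, but both would give this, so that they cannot be told apart. Ifi202b on chromosome 1, which is known to differ between inbred strains, had 2 counts over all IRE1KO libraries and 647 over all WT libraries. This is a ratio of 422.1 (95% counting interval 116.4 to 3493). Lying on another chromosome, it does not decide between linked alleles and an effect of Ern1 loss. A difference in strain background beyond the chromosome of Ern1 could add to the 72 calls elsewhere, and it was not tested.

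WT library 1 lay apart from the other WT libraries, and without it the count rose to 1192. On the 44 genes near Ern1 called without it, it held a median position of 0.391, where 0 is the mean of the other WT libraries and 1 the IRE1KO mean, and with each IRE1KO library held out beside it in turn it lay at 0.288 to 0.357 on 16 to 23 such genes, against 0.852 to 1.01 for the held-out IRE1KO library, which argues against a mislabelled IRE1KO library. Fewer glial cells alone would leave genes of other cells in place. On 1114 other genes called without WT library 1 its position was 0.926 (0.795 to 0.830 with an IRE1KO library held out too, against 0.895 to 1.02 for that library). Only the listed glial and Schwann cell genes had been set aside, so unlisted genes of such cells may be among the 1114. The test therefore does not decide whether fewer glial cells account for the pattern. Its low Y-linked expression may matter, as the count was 952 with that level as a covariate, but the covariate of interferon-stimulated genes gave 1781, so an effect of sex cannot be told apart from another difference between the WT libraries. The genotype of the pups in each pool was not tested.

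Glial markers were lower in IRE1KO. As small a camera p, in either direction, came up in 2 of 100 splits, the real one included (real p 2.40e-07, smallest other 2.75e-08). The other split, with the smaller p, set IRE1KO libraries 1, 3, 4 and 5 against IRE1KO library 2 and the WT libraries. The share is under the 5% set beforehand for excluding chance, but it does not allow for the choice of this list among those tested. The call is also lost with an estimated correlation (camera adjusted p = 0.148). A larger share of the main cell type would lower the markers of every other type alike, but the glial score minus the macrophage score was -2.32 ± 0.4996 (SD, n = 5) in IRE1KO and -0.90 ± 0.796 (SD, n = 4) in WT (exact permutation test, two-sided, p = 0.00794, the smallest that 126 splits allow), so it does not account for the pattern alone. Most adipocyte (5 of 6), chondrocyte (14 of 15), endothelial (8 of 9) and muscle markers (8 of 9) had negative fold changes as well, so a lower share of several other cell types beside a rise of macrophages stays open. Fewer Schwann-like cells in the IRE1KO cultures may account for it: 18 further Schwann cell genes had a median log2 fold change of -0.77, 17 of them negative (camera p = 9.59e-06, but p = 0.0939 with an estimated correlation) and 0 called by edgeR. Among the most abundant of them, Matn2 was at 75.3 ± 6.91 CPM in IRE1KO and 128.3 ± 82.4 CPM in WT, and Adam23, which did not differ in this way, at 279.3 ± 35.1 and 289.8 ± 105.2 CPM. The sort for Osx1-Cre cells would be expected to remove such cells, and a change of these genes within the sorted cells was not tested.

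Interferon-stimulated genes varied between libraries of 1 genotype. Over the 9 libraries their score correlated with that of macrophage markers (Pearson's r = 0.879, permutation p = 0.00367, adjusted p = 0.0110 over 3 tests; Spearman's rho = 0.817, permutation p = 0.0107, adjusted p = 0.0160). Without WT library 2 and IRE1KO library 3, the 2 farthest from the median macrophage score, r was 0.733 with a permutation p of 0.0618, so that over the remaining 7 libraries the relation no longer passed. Macrophages in the culture, which the sort for Osx1-Cre cells would be expected to remove, may be a source of the signal, with Lyz2 at 111.1 ± 39.4 CPM in IRE1KO and 105.3 ± 45.3 CPM in WT, but whether an interferon response of the bone cells accompanied them cannot be told apart from these data.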
